A study of Sus scrofa with 11 samples.

How the data were processed

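Gene expression was measured in left ventricular tissue of male Yorkshire pigs, taken from the ischemic territory of hearts in which an ameroid constrictor, a ring that swells and slowly closes the vessel, had been placed on the left circumflex coronary artery. Per the labels, pigs ate a normal diet (ND) or a high fat diet (HFD) for 12 weeks, the heart muscle was injected with vehicle or with extracellular vesicles (EV), membrane particles released by cells, and tissue was collected 5 weeks after the injection. The 11 arrays fell into ND (3), ND+EV (3), HFD (2) and HFD+EV (3), as their titles state. The titles call the samples of a group biological replicates. No label tied an array to a named animal.

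Per the labels' protocols, 50 ng of total RNA was hybridised to an Affymetrix whole-transcript array, and the submitters' processing notes name Transcriptome Analysis Console, with no version. The authors deposited normalized log2 signal per probe set, which is the unit of every value here. The summary and normalization method, the array annotation version and the genome build are not given in the sources used here, so no coordinates are printed. The table held 27558 probe sets, with values from 2.14 to 14.02 and array medians from 4.36 to 4.48. No probe set was centred. The scale is the base-2 logarithm because the range is that of log2 array signal and the tool named writes it so. A detection call per probe set was not used here. The number of arrays limits the precision of every value.

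Genes were named from the platform annotation, which can be old. It gave 1 symbol for 13157 probe sets, several for 523 and none for 13878, and no gene was named from a probe set with several. Of the probe sets with 1 symbol, 12841 matched a current gene table by gene ID, which updated 7 symbols. The probe set reported as PDIA2 carried the symbol RGS11 in the platform annotation. In the table, 1239 probe sets shared all their values with another one, and each was tested. Control probe sets were not identified in the annotation used here.

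The 25% of probe sets with the lowest mean signal (below 3.63) were left out, which left 20668. A linear model with 1 mean per group over all 11 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 7 residual and 3.62 prior degrees of freedom). Each of 7 contrasts was tested, two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The contrasts were EV under each diet, the difference of these EV effects, diet under each injection, and both mean effects. Fold changes are differences of log2 means, given with their limma standard error (SE). Each gene's value comes from its probe set with the highest mean signal. Among the genes named, probe sets of KDR, DLAT and YJEFN3, and of VEGFA in HFD+EV against ND+EV, pointed in opposite directions.

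Gene lists for the tissue and treatment were fixed before the data were examined, as were the groups, tests, alternatives and the rule for naming genes. Of 58 lists (40 for pathways or complexes and 18 for cell types), 51 had at least 5 measured members. The 7 lists left out held markers of lymphatic endothelium, neutrophils, mast cells, nerve, red cells, platelets and skeletal muscle. Lists were tested over 9738 genes with camera at a preset correlation of 0.01, with adjustment over the 51 lists of a contrast. The same test with an estimated correlation, and fry, were run beside it. The fry p tests whether a list's genes move, on balance, one way, and does not compare them with other genes. With an estimated correlation, interferon-stimulated genes were the only list to hold, in HFD+EV against HFD, HFD+EV against ND+EV, the difference of the EV effects and the mean EV effect. A list score is the mean over a list's genes of the log2 signal on an array minus that gene's mean over all arrays.

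The rule for named genes took, for each contrast, up to 8 higher and 8 lower genes past the threshold with a fold of at least 1.5, ordered by fold, and filled the places with the smallest unadjusted p among genes at that fold whose groups did not overlap, which are given as not having passed. It added the 3 members with the smallest p of each list past its threshold, and 14 angiogenesis genes as a group. For the difference of the EV effects and the mean effects, members were named only for lists not described before, and uncharacterised loci were counted but not named.

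The functions were tested on simulated data with the real means and standard deviations of 20668 probe sets and 200 changed genes. In ND+EV against ND, 70.1% of genes changed by a fold of 2 and 95.5% of those changed by a fold of 4 were recovered. In HFD against ND the shares were 43.3% and 92.4%, in HFD+EV against HFD 41.8% and 93.9%, and in HFD+EV against ND+EV 68.7% and 95.5%. Of genes changed by a fold of 1.5, between 11.9% and 25.4% were recovered in these 4 comparisons. Genes called that had not been changed numbered 15 of 133 calls in ND+EV against ND, a share above the threshold of 0.05, 5 of 103 in HFD+EV against HFD, 2 of 100 in HFD against ND and 4 of 130 in HFD+EV against ND+EV. Noise was drawn independently for each gene, with the same spread on every array and no trend with signal level between arrays. Real arrays do not follow this, so the shares recovered may not hold for them.

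The alternatives covered the filter, the variance prior, quantile normalization, centring, array weights, fits with only the groups compared, a replicate block, probe sets with 1 symbol, the list test, the choice of probe set per gene and each array left out. Cyclic loess normalization, identical probe sets counted once, and fits without ND arrays 1 and 3, with and without HFD+EV array 1, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.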

Results

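Whole-transcript arrays compared the ischemic left ventricle of pigs on a normal or a high fat diet, with vehicle or EV injected into the muscle. ND had 3 arrays, ND+EV 3, HFD 2 and HFD+EV 3. The series asks how the diet bears on the angiogenic response to EV. ND replicates 1 and 3 stood apart from the other arrays, with mean correlations to the rest of 0.925 and 0.937 against 0.951 to 0.962 for the other 9. These 2 arrays had the smallest spread of log2 signal (SD 1.45 and 1.47), and HFD replicates 1 and 2 and HFD+EV replicate 3 had the largest (1.59, 1.62 and 1.60). The first principal component held 35.8% of the variance and placed HFD+EV replicate 1 (0.14) on the side of ND replicates 1 (0.62) and 3 (0.34), opposite HFD replicate 2 (-0.42).

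The first comparison asked what EV did under the normal diet. Genes of nuclear-encoded respiratory chain subunits, cytosolic ribosomal proteins and the proteasome were higher in ND+EV than in ND, each as a set by camera (adjusted p = 0.895 for each with an estimated correlation). The median log2 fold change was 0.70 for 27 respiratory chain genes, all higher (camera adjusted p = 3.4e-14). NDUFV2, a subunit of complex I, had a log2 signal of 8.93 ± 0.09 in ND+EV and 8.23 ± 0.27 in ND (SD, n = 3 each; limma adjusted p = 0.539). All 33 ribosomal protein genes (median 0.47, RPL32 0.74) and all 16 proteasome and ubiquitin ligase genes (median 0.51, PSMA6 1.02, or 0.66 without ND replicate 1, PSMB6 0.85) were also higher, with the same adjusted p of 0.895 with an estimated correlation. Fold changes in this comparison correlated with mean signal across probe sets (r = 0.238).

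Further sets past the threshold of camera in ND+EV, and not with an estimated correlation (adjusted p = 0.895), were the TCA cycle (13 of 14 genes higher, median 0.32), ketone and branched-chain amino acid breakdown (12 of 14, 0.30), complement (12 of 13, 0.20), fatty acid oxidation (15 of 17, 0.24) and oxidative stress genes (12 of 15, 0.22). Their members with the smallest p included SLC25A20, the mitochondrial carrier of acylcarnitines (0.60), PCCB of propionate breakdown (0.56), the isocitrate dehydrogenase subunit IDH3A (0.38), the complement protease C1R (0.60) and the peroxidase PRDX1 (0.53). Of the 8 lists 0 passed fry. Adjusted over the list alone, 13 respiratory chain genes, 3 proteasome genes and 1 fatty acid oxidation gene passed, against 0 over all genes. Such counts for a list that passed camera come from the values that picked it and are no separate support. Respiratory chain, ribosomal protein and proteasome genes passed camera without any 1 array. ND replicate 1 still carried much of their size. On ND replicates 1, 2 and 3 the respiratory chain scores were -1.10, -0.14 and -0.45 (mean 0.11 in ND+EV). Those of ribosomal proteins were -0.89, 0.085 and -0.088 (0.23), and those of the proteasome -0.83, -0.16 and -0.54 (0.032). Without ND replicate 1 these 3 lists alone passed (TCA cycle, camera adjusted p = 0.226, ketone and branched-chain amino acids 0.112, complement 0.318, fatty acid oxidation 0.318, oxidative stress 0.428). The scores of the lists lost were lowest on that array, at -0.62, -0.49, -0.66, -0.44 and -0.55 in this order. Without ND+EV replicate 2, 5 lists passed (fatty acid oxidation, camera adjusted p = 0.145, ketone and branched-chain amino acids 0.0585, oxidative stress 0.131). The call also ended for fatty acid oxidation without ND+EV replicate 1 (0.0841), and for complement (0.0964) and oxidative stress (0.0603) without ND+EV replicate 3. Without both ND replicates 1 and 3 the medians were 0.29 for the respiratory chain (camera adjusted p = 0.0046), 0.14 for ribosomal proteins (0.0457) and 0.18 for the proteasome, which did not pass (0.0726), and 2 of the 8 lists passed. Under cyclic loess the TCA cycle (0.19), fatty acid oxidation (0.214), complement (0.058) and oxidative stress (0.131) did not pass.

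No single gene passed in ND+EV against ND. With limma, 0 of 20668 probe sets passed and 1758 had an unadjusted p under 0.05. The groups did not overlap at 11.6% of probe sets, where chance gives 10%. The named genes with the smallest p were RNGTT, the mRNA capping enzyme (log2 fold change 0.94 ± 0.15, SE), and YJEFN3 (-1.19 ± 0.19), both with adjusted p = 0.346. SKA2 (1.13), UBE2L3 (0.84), HPRT1 (0.71), CYYR1 (0.87), ERGIC2 (0.60), the relaxin receptor RXFP1 (0.72) and the autophagy protease ATG4A (0.75) were higher in all 3 ND+EV arrays and did not pass. HOOK2 (-0.79), SPRED2 (-0.62), AKAP13 (-0.66), ZBED3 (-0.71), IGF1R, the receptor of insulin-like growth factor 1 (-0.60), GFOD1 (-0.70) and RAB40B (-0.69) were lower in all 3 and did not pass.

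VEGFA, the main vascular endothelial growth factor, had the smallest p of the fixed angiogenesis genes in this comparison (probe set 15310081). Its log2 signal was 9.44 ± 0.25 in ND+EV and 10.09 ± 0.38 in ND (SD, n = 3 each), lower in all 3 EV arrays, with a log2 fold change of -0.65 ± 0.19 (SE) and a limma adjusted p of 0.549. Without ND replicate 1 it was -0.43. Of the 14 genes 11 were measured, 5 higher and 6 lower. Adjusted over the list alone 0 passed, as over all genes, and 1 had an unadjusted p under 0.05.

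**Figure D1:**
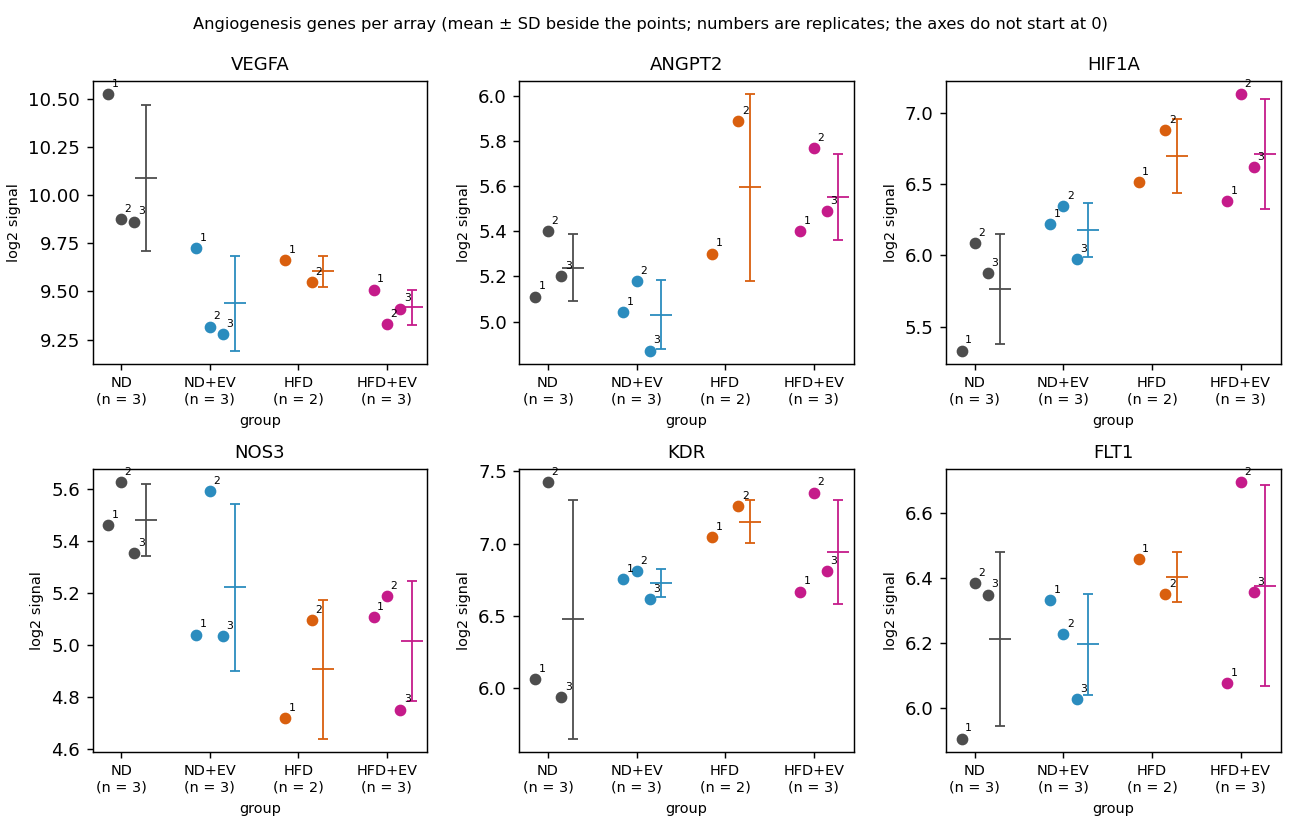
Log2 signal of VEGFA, ANGPT2, HIF1A, NOS3, KDR and FLT1 on each array (vertical axes, not starting at 0) by group (horizontal axes), with points numbered by replicate and the mean ± SD of each group beside them. VEGFA was lower in all 3 ND+EV arrays than in the 3 ND arrays, and HIF1A had group means of 6.70 and 6.71 under the high fat diet against 5.77 and 6.18 under the normal diet.

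The second comparison asked the same of EV under the high fat diet. Interferon-stimulated genes, which cells switch on in response to interferon, rose in HFD+EV: all 19 measured genes were higher than in HFD, with a median log2 fold change of 0.67 (camera adjusted p = 1.5e-22, and 0.00087 with an estimated correlation, or 0.104 in a fit of these 5 arrays alone). The list score was 0.56, 0.60 and 0.46 on the 3 HFD+EV arrays and -0.08 or below on the other 8. MX2, an antiviral GTPase (probe set 15218800), had a log2 signal of 6.94 ± 0.29 in HFD+EV (SD, n = 3) and 5.19 ± 0.03 in HFD (n = 2), a fold of 3.36 (limma adjusted p = 0.427). IFIT1 (0.88), an inhibitor of viral RNA translation, and UBA7 (1.11), which activates the ubiquitin-like protein ISG15, followed. Adjusted over the list alone 13 of the 19 genes passed, against 0 over all genes.

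Camera passed 8 further lists in HFD+EV against HFD, each with an adjusted p of 0.615 or 0.633 with an estimated correlation. Antigen presentation genes were higher as a set (17 of 18, median 0.21; 0.615 with an estimated correlation), led by the peptide transporter TAP1 (0.76), with CTSS (0.38) and the immunoproteasome subunit PSMB9 (0.37). Cell cycle genes (11 of 12, median 0.18; CENPF 0.25) and immediate early genes (11 of 14, 0.24; CYR61 0.32) were higher too (0.615 each with an estimated correlation), and without HFD+EV replicate 3 the immediate early median was 0.04 (camera adjusted p = 0.999). Lists on the lower side in HFD+EV, with 0.633 for collagen and 0.615 for the others with an estimated correlation, were cardiac stress and fetal genes (all 13 lower, median -0.66), heat shock (13 of 14, -0.31), fibrillar collagen and matrix (19 of 23, -0.21), glycolysis (14 of 15, -0.18) and the unfolded protein response (14 of 20, -0.27). Among them were XIRP2, an actin-binding protein of the intercalated disc (-1.94), the stress-responsive ANKRD1 (-0.66), the small heat shock proteins CRYAB (-0.71) and HSPB1 (-0.66), VCAN (-1.10), COL6A3 (-0.73), HK2 (-0.47), ENO1 (-0.76) and HSPA5 (-0.43). Without HFD replicate 1 VCAN was -1.68, CTSS 0.085, PSMB9 0.23 and CYR61 0.20, and without HFD replicate 2 VCAN was -0.51, COL6A3 -0.44, CTSS 0.67 and HSPA5 -0.26. ENO1 (-0.43), CRYAB (-0.46) and HSPA5 (-0.26) moved as much without HFD+EV replicate 1, PSMB9 (0.21) without HFD+EV replicate 2 and CYR61 (0.21) without HFD+EV replicate 3. Without HFD replicate 2 the cardiac stress median was -0.32 (camera adjusted p = 0.080), and the collagen median was 0.004 (0.895). The heat shock call held without any 1 array. Calls that ended without HFD replicate 1 were antigen presentation (0.188), glycolysis (0.0637), immediate early (0.0637) and cell cycle genes (0.439), and without HFD replicate 2 also immediate early genes (0.127) and the unfolded protein response (0.847). Without HFD+EV replicate 1 collagen (0.371), glycolysis (0.237) and the unfolded protein response (0.407) did not pass, nor did cell cycle genes without HFD+EV replicate 2 (0.0516) or 3 (0.0568). The unfolded protein response call also ended without ND replicate 1 (0.051), ND replicate 3 (0.0601) or ND+EV replicate 3 (0.056). These 3 arrays are not among those compared. The unfolded protein response score was 0.12 and 0.49 on HFD replicates 1 and 2, against a mean of 0.098 in HFD+EV. For antigen presentation these scores were -0.11 and 0.15 against 0.23, and for cell cycle genes -0.26 and -0.073 against -0.019. Under cyclic loess glycolysis (0.0902), collagen (0.0516), the unfolded protein response (0.079) and cell cycle genes (0.079) did not pass. Without HFD+EV replicate 2, 14 lists passed in place of 9. Atrial markers, genes of atrial muscle, did not pass (7 of 8 lower, median -0.15, camera adjusted p = 0.0963), with scores of 0.21 and 0.76 on HFD replicates 1 and 2 and a mean of -0.10 in HFD+EV.

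**Figure D2:**
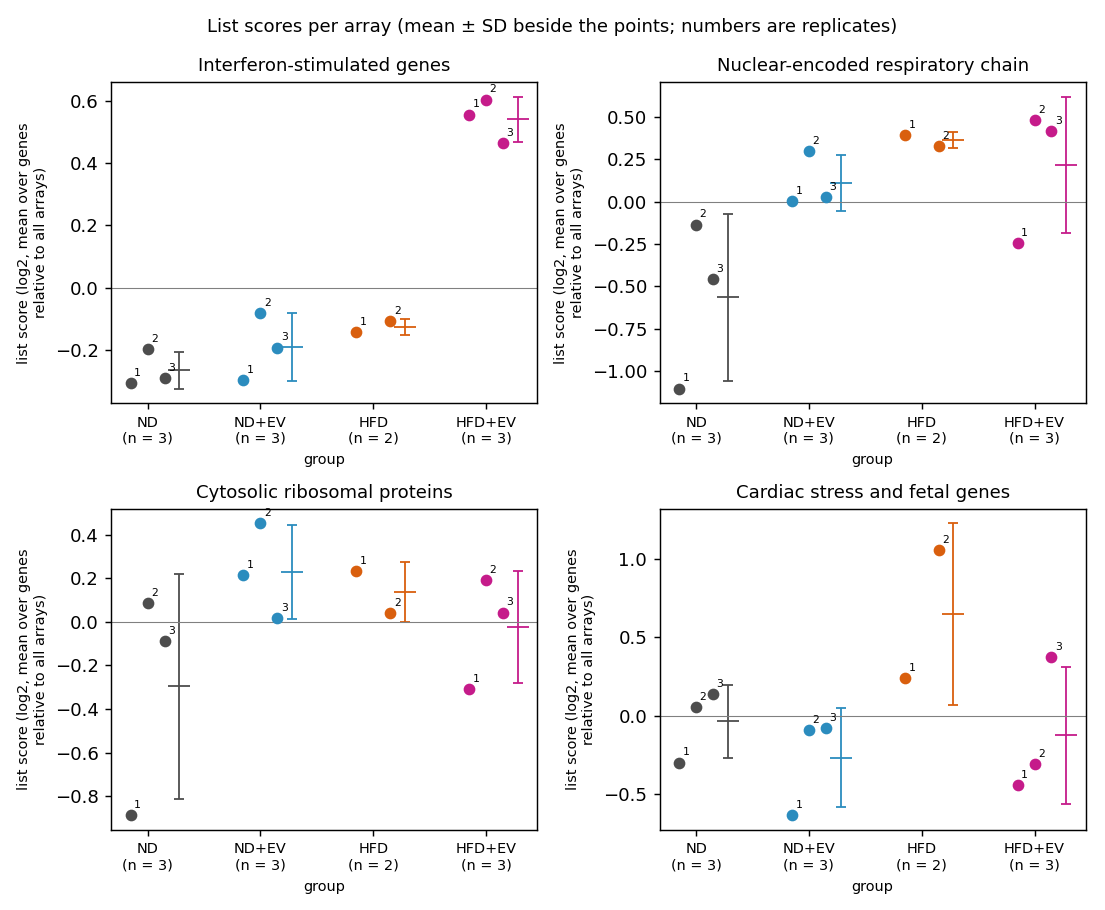
List scores on each of the 11 arrays (vertical axes, log2 relative to the mean of all arrays) by group (horizontal axes), with points numbered by replicate and the mean ± SD of each group beside them. Interferon-stimulated genes lay between 0.46 and 0.60 on the 3 HFD+EV arrays and at -0.08 or below on the others, while ND replicate 1 lay lowest in the respiratory chain and ribosomal protein panels.

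No single gene passed in HFD+EV against HFD. With limma, 0 probe sets passed and 1146 had an unadjusted p under 0.05, and the groups did not overlap at 23.2% of probe sets, where chance gives 20%. Fold changes correlated with mean signal across probe sets at r = -0.157. PCP4L1 had the smallest p of the named genes (probe set 15279678), with a log2 signal of 4.59 ± 0.05 in HFD+EV and 6.25 ± 0.63 in HFD (adjusted p = 0.341). The higher genes given by the rule, none of which passed, were FHL5 (0.91), ISG12(A) (1.25), MX2, the galectin LGALS9 (1.33), the microRNA gene MIR181A-2 (1.07), IFIT1, UBA7 and CDHR4 (0.76). The lower ones were TRAPPC4 (-0.86), GNB5 (-0.84), SNX24 (-0.97), TSPYL4 (-1.02), the ephrin EFNB1 (-0.79), the calcium store protein CASQ1 (-1.24) and PDIA2 (-1.30), which did not pass either. Of the fixed angiogenesis genes 5 were higher and 6 lower, ANGPT1 (0.15), FGF2 (0.25) and VEGFA (-0.19) had the smallest p, and 0 passed adjusted over the list alone or over all genes. FGF2 was -0.20 without HFD replicate 1, 0.69 without HFD replicate 2 and 0.069 without HFD+EV replicate 1.

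The difference of the EV effects, HFD+EV minus HFD less ND+EV minus ND, tested whether the diet changed the response. For interferon-stimulated genes the difference between EV and vehicle arrays was larger under the high fat diet. All 19 genes were higher, with a median difference of 0.57 (camera adjusted p = 1.7e-10, and 0.0101 with an estimated correlation). In ND+EV against ND their median was 0.06 (camera adjusted p = 0.68). A shared exposure or processing batch of the HFD+EV arrays was not tested, so the difference is not shown to be a response to EV. The call for the difference held with an estimated correlation in 19 of 20 settings, with medians from 0.51 to 0.655. MX2 differed by 1.65 ± 0.44 (SE), UBA7 by 1.13 ± 0.33 and IFIT1 by 0.82 ± 0.25. Adjusted over the list alone 5 genes passed, against 0 over all genes.

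In 9 lists the EV effect was lower under the high fat diet than under the normal diet (adjusted p = 0.651 for each with an estimated correlation): respiratory chain (-0.76), ribosomal proteins (-0.67), proteasome (-0.72), TCA cycle (-0.51), heat shock (-0.45), glycolysis (-0.47), collagen and matrix (-0.56), ketone and branched-chain amino acid breakdown (-0.45) and sarcomere (-0.22). For immediate early genes it was higher (0.24; 0.651 with an estimated correlation). In the sarcomere list TPM1 (-0.80), ACTA1 (-0.67) and TCAP (-0.65) had the smallest p, with TPM1 at -0.50 without HFD+EV replicate 1 and TCAP at -0.41 without ND replicate 1 and -0.99 without ND replicate 3. The sarcomere median turned to 0.19 under cyclic loess. The calls for respiratory chain, ribosomal proteins, proteasome, TCA cycle and heat shock held without any 1 array, and all 5 ended without ND replicates 1 and 3 and HFD+EV replicate 1. The medians were then -0.16 (camera adjusted p = 0.0918), -0.17 (0.0998), -0.22 (0.407), -0.10 (0.458) and -0.16 (0.407). Heat shock also failed without both ND replicates 1 and 3 (0.0674), and under cyclic loess the TCA cycle (0.0999), glycolysis (0.291), collagen (0.161) and ketone and branched-chain amino acids (0.124) failed. Without HFD+EV replicate 1, 7 lists passed in place of 11, with glycolysis (0.071), collagen (0.159), sarcomere (0.219) and ketone and branched-chain amino acids (0.219) lost. The last of these also ended without ND replicate 1 (0.128), ND+EV replicate 2 (0.118) or HFD replicate 1 (0.523), and collagen without ND replicate 1 (0.231) or HFD replicate 2 (0.51). The sarcomere call ended without ND replicates 1 (0.13) or 2 (0.0813), ND+EV replicates 2 (0.118) or 3 (0.0517) or HFD replicate 1 (0.345). The immediate early call ended without ND replicates 2 (0.0813) or 3 (0.249), ND+EV replicate 3 (0.153), HFD replicate 2 (0.124) or HFD+EV replicate 3, where the median turned to -0.058 (0.633). The score of that array was 0.66, and at most 0.08 on the other 10. Collagen and matrix scores were 0.078 and 0.72 on HFD replicates 1 and 2, and -0.69, -0.17 and 0.22 on ND replicates 1, 2 and 3.

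With limma 0 probe sets passed for the difference of the EV effects and 1740 had an unadjusted p under 0.05. The differences correlated with mean signal across probe sets (r = -0.261). The genes with the smallest p were PCP4L1 (-1.82), ATG4A (-1.30), CDHR4 (1.11), MIR181A-2 (1.40), FAM160A2 (0.90), TRAPPC4 (-0.97), the cysteine dioxygenase CDO1 (-1.28), MED10 (-0.83), HPRT1 (-1.001), FHL5 (0.89), TSPYL4 (-1.26), RRAGC (-0.79), DDI1 (1.11), TAP1 (1.05), the cholesterol exporter ABCA1 (0.88) and LRRC71 (0.67), all with adjusted p = 0.572. VEGFA differed by 0.46 ± 0.28 (SE; 0.24 without ND replicate 1), and 0 of the 11 fixed angiogenesis genes passed adjusted over the list alone or over all genes. Across the 20668 probe sets, which are not independent replicates, the EV effects in the 2 diets correlated at -0.16 (Pearson and Spearman), and at 0.015 without ND replicate 1 or 0.0082 without HFD+EV replicate 1.

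The fourth comparison asked how the diet differed in hearts injected with vehicle. Single genes passed here, among them genes of mitochondria and the proteasome. TOMM22, a receptor of the mitochondrial import complex, had a log2 signal of 7.51 ± 0.003 in HFD (SD, n = 2) and 5.34 ± 0.31 in ND (n = 3), a fold of 4.52 (limma adjusted p = 0.0471). PSMD8, a proteasome subunit, rose 3.61-fold and PCP4L1 3.85-fold, with the same adjusted p. UBE2B (1.78), FAM129A (1.77), the matrix protein SPON1 (1.65), SKA2 (1.59) and TMED2 (1.42) rose as well, and DDI1 (-1.26), MIR181A-2 (-1.20), CCDC38 (-0.81), the platelet receptor CLEC1B (-0.74) and LRRC71 (-0.65) fell, beside 3 uncharacterised loci.

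In all, 152 probe sets passed in HFD against ND, 106 higher and 46 lower, with 64 named genes among them. The groups did not overlap at 39.1% of probe sets, where chance gives 20%. Every adjusted p that passed lay between 0.0471 and 0.0492, and 4963 probe sets had an unadjusted p under 0.05. The count was 0 with no filter, quantile normalization, cyclic loess or array weights and without both ND replicates 1 and 3. Leaving out 1 array gave 1 without ND replicate 1, 1356 without ND replicate 2, 12 without ND replicate 3, 7 without HFD replicate 1, 722 without HFD+EV replicate 1, and 0 without any one of HFD replicate 2, HFD+EV replicates 2 and 3 and the 3 ND+EV arrays.

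As a set, 26 of 27 respiratory chain genes were higher in HFD (median 0.95, camera adjusted p = 2.6e-08, and 0.453 with an estimated correlation), and 3 passed over all genes and 19 adjusted over the list alone. ATP5A1, a subunit of ATP synthase (1.32, adjusted p = 0.0471), and NDUFS3 of complex I (1.24) rose. All 16 proteasome genes were higher (median 0.86; 0.453 with an estimated correlation), 5 passed over all genes and 12 adjusted over the list alone, PSMD12 among them (1.22). The TCA cycle (14 of 14, 0.63; DLAT 1.08), heat shock (14 of 14, 0.61; HSPE1 1.11), EV biogenesis (14 of 15, 0.64; SDCBP 1.04), ketone and branched-chain amino acid breakdown (13 of 14, 0.68; DLD 1.10) and glycolysis (13 of 15, 0.53; LDHA 1.15) lists were higher too, each with 0.453 with an estimated correlation. Camera also passed collagen and matrix (0.69; POSTN 1.46), ribosomal proteins (0.44; RPS27A 0.89, or 0.58 without ND replicate 1), fatty acid oxidation (0.48; HADH 0.85), cardiac stress genes (0.61; ANKRD1 0.87) and fibroblast markers (0.59; LUM 1.04, or 0.57 without ND replicate 1 and 0.64 without HFD replicate 2), with adjusted p from 0.453 to 0.753 with an estimated correlation.

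The remaining lists higher in HFD by camera, with 0.453 to 0.549 with an estimated correlation, were signalling through AKT, mTOR and MAPK (0.34), the unfolded protein response (0.47), sarcomere (0.35; -0.14 under cyclic loess), oxidative stress (0.35), insulin and glucose handling (0.35), HIF targets (0.21) and complement (0.42). In them MAPK8 (0.89), the chaperone CALR (0.99) and the glycogen phosphorylase PYGM (1.21) rose, and TPM1 (0.86), PRDX6 (1.59), EGLN1 (0.59) and C7 (1.25; 0.74 without HFD replicate 2) were higher without passing. Cell cycle genes (-0.17; HMMR -0.42), mitochondrially encoded genes (-0.21; ND3 -0.60) and B and plasma cell markers (-0.29; CD79B -0.81) were lower, with 0.453 to 0.600 with an estimated correlation. None of the 22 lists held with an estimated correlation, where the smallest adjusted p was 0.453, and 19 lists passed fry. The calls for the respiratory chain, proteasome, TCA cycle, heat shock, EV biogenesis and glycolysis held without any 1 array. Under cyclic loess 6 lists passed, and glycolysis (0.0906), EV biogenesis (0.0564), collagen (0.0906), fatty acid oxidation (0.193), cardiac stress (0.462), fibroblast (0.413), ribosomal protein (0.831, median 0.13) and insulin handling genes (0.831, median 0.034) were among those that did not. Without ND replicate 1, 11 lists passed camera, with ribosomal proteins (camera adjusted p = 0.563), complement (0.211), fibroblast markers (0.132), HIF targets (0.0995), mitochondrially encoded genes (0.0792), B and plasma cell markers (0.0779), collagen (0.0766), cardiac stress, insulin handling and oxidative stress (0.0715 each) and sarcomere (0.0617) lost. Without HFD replicate 1, 13 did, with cell cycle (0.272), sarcomere (0.197), ribosomal proteins (0.143), HIF targets (0.119), insulin handling (0.108), B and plasma cell markers (0.108), ketone and branched-chain amino acids (0.0992), mitochondrially encoded genes (0.0884) and fatty acid oxidation (0.0559) lost. Without HFD replicate 2, cardiac stress (0.427), collagen (0.272), unfolded protein response (0.257), fibroblast (0.214), complement (0.125), mitochondrially encoded (0.112) and B and plasma cell genes (0.0502) did not pass. Without ND replicate 3, mitochondrially encoded genes (0.146), AKT, mTOR and MAPK, cell cycle and B and plasma cell genes (0.0925 each), HIF targets (0.0818) and insulin handling (0.0613) did not, and without ND replicate 2 insulin handling and complement (0.0539 each) did not. Mitochondrially encoded genes also failed without ND+EV replicate 1 (0.0506), ND+EV replicate 3 (0.0509) or HFD+EV replicate 2 (0.0501), and B and plasma cell markers without HFD+EV replicate 1 (0.0526). These EV arrays are not among those compared. On HFD replicates 1 and 2 the scores were 0.24 and 1.055 for cardiac stress genes (mean -0.037 in ND) and 0.078 and 0.72 for collagen (-0.21 in ND). Atrial markers had 0.21 and 0.76 on the same arrays (-0.17 in ND). The ribosomal protein score was -0.89 on ND replicate 1, against 0.085 and -0.088 on ND replicates 2 and 3. Fold changes correlated with mean signal across probe sets (r = 0.337). Without both ND replicates 1 and 3 the medians were 0.46 for the respiratory chain, 0.49 for the proteasome and 0.057 for ribosomal proteins.

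Of the 11 fixed angiogenesis genes 8 were higher and 3 lower in HFD than in ND. HIF1A, the hypoxia-induced transcription factor, was higher by 0.93 ± 0.26 (SE; limma adjusted p = 0.0807). NOS3, the endothelial nitric oxide synthase, had -0.57 ± 0.21, VEGFA -0.48 ± 0.21 (-0.26 without ND replicate 1) and the angiogenesis inhibitor THBS1 0.88 ± 0.42. None passed, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05.

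The fifth comparison set the diets against each other in hearts that received EV. All 19 interferon-stimulated genes were higher in HFD+EV than in ND+EV, with a median log2 fold change of 0.73 (camera adjusted p = 4.1e-20, and 0.0013 with an estimated correlation). IFI44 (0.73), the viral RNA sensor IFIH1 (0.83), MX2 (1.41) and the kinase EIF2AK2 (0.91) were higher in all 3 arrays. Adjusted over the list alone 16 genes passed, against 0 over all genes. In a fit of these 6 arrays alone, the adjusted p with an estimated correlation was 0.069, and without ND replicates 1 and 3 and HFD+EV replicate 1 it was 0.123.

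Antigen presentation (16 of 18, median 0.24; TAP1 0.93), the unfolded protein response (17 of 20, 0.21; CALR 0.52), EV biogenesis (13 of 15, 0.26; RAB27B 0.50, or 0.25 without HFD+EV replicate 1) and angiogenic ligands and receptors (18 of 21, 0.18; ANGPT2 0.52, VEGFC 0.31, HGF 0.24) were also higher in HFD+EV by camera, with an adjusted p of 0.797 for each with an estimated correlation. Ribosomal protein genes were lower (30 of 33, -0.26; RPL34 -0.41, or -0.24 without ND+EV replicate 2), also with 0.797. Without HFD+EV replicate 1, 18 lists passed in place of 6, and without ND+EV replicate 2, 12 did. Antigen presentation and ribosomal proteins passed without any 1 array. Under cyclic loess antigen presentation (0.0563), the unfolded protein response (0.0668), EV biogenesis (0.138) and the angiogenic list (0.138) did not pass. Without ND replicate 3 or HFD+EV replicate 3, 3 lists passed, with angiogenic ligands and receptors (0.0504 and 0.0719), unfolded protein response (0.0504 and 0.197) and EV biogenesis (0.0504 and 0.117) lost. The angiogenic list was also lost without ND+EV replicate 2 (0.146), ND+EV replicate 3 (0.0998) or HFD+EV replicate 1 (0.0528). The other 2 were lost without ND+EV replicate 1 (0.0938 and 0.0613) or HFD+EV replicate 2 (0.0515 and 0.124). The mean score of the angiogenic list was 0.061 in HFD+EV and -0.106 in ND+EV, and 0.137 in HFD and -0.046 in ND. It was thus not higher with EV than with vehicle under either diet, and the diets differed in the same direction with vehicle.

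With limma 0 probe sets passed in HFD+EV against ND+EV and 1522 had an unadjusted p under 0.05; the groups did not overlap at 14.5%, where chance gives 10%. The higher genes given by the rule were GVIN1, an interferon-inducible GTPase (1.19 ± 0.19, SE; adjusted p = 0.197), TAP1, IFI44, PHF11 (0.73), IFIH1, MX2, the phosphodiesterase PDE2A (0.69) and EIF2AK2. The lower ones were MYL7, the atrial myosin light chain (-2.15 ± 0.55), MIR885 (-0.91), MIP (-0.62), L3MBTL1 (-0.76), NAP1L5 (-0.73), MDFI (-0.64), RBM24 (-0.68) and the oxysterol receptor NR1H3 (-0.73). None passed. Of the fixed angiogenesis genes, ANGPT2 (0.52) and HIF1A (0.53) had an unadjusted p under 0.05, and 0 passed adjusted over the list alone or over all genes. HIF1A was 0.32 without HFD+EV replicate 2.

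**Figure D3:**
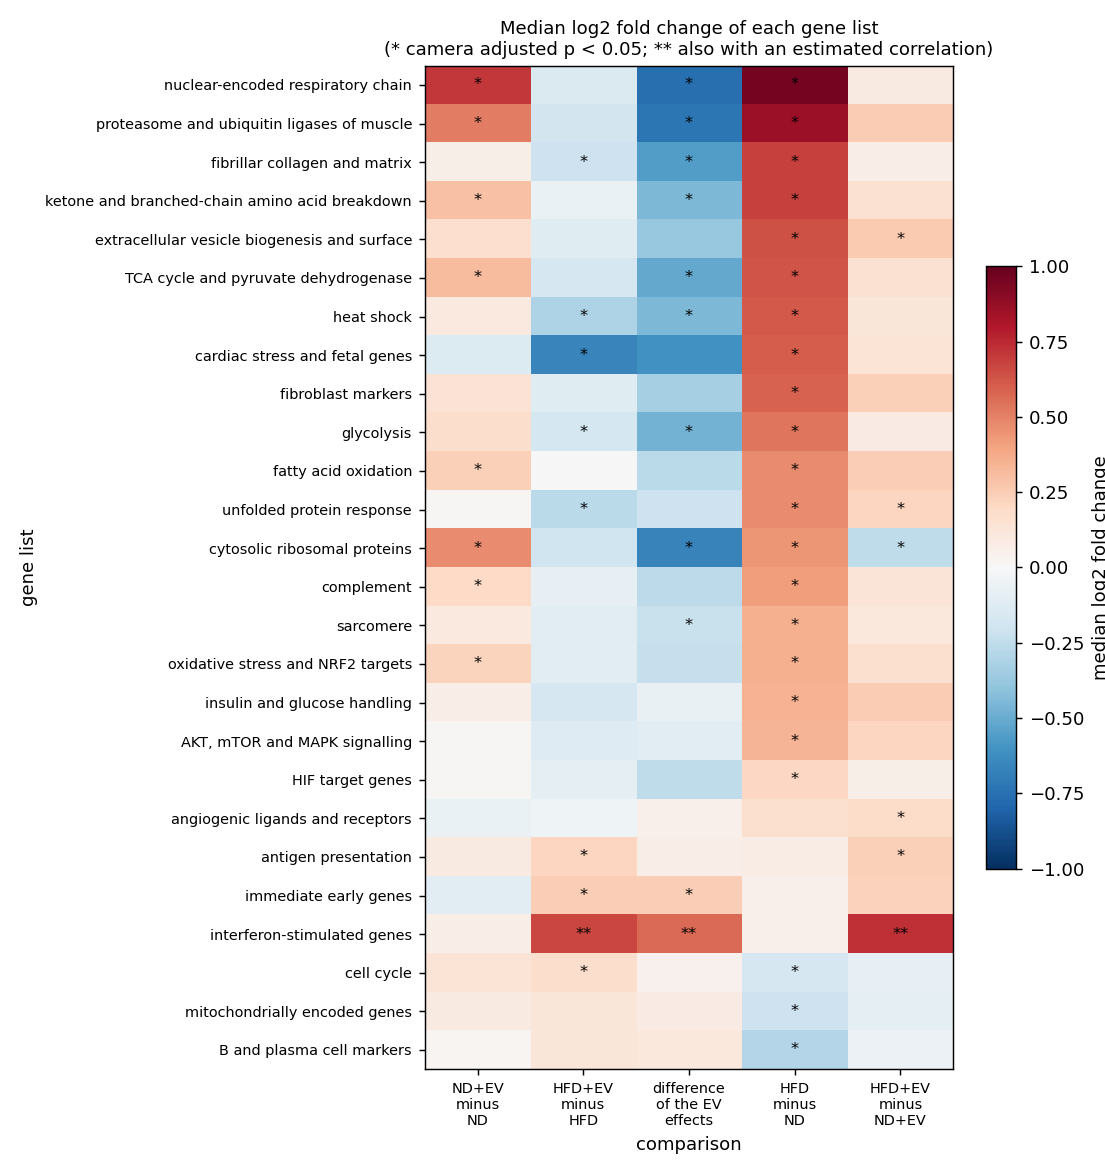
Median log2 fold change (colour) of each gene list (rows) that passed camera in at least 1 of the 5 comparisons (columns), with 1 asterisk for a camera adjusted p under 0.05 and 2 where the call also held with an estimated correlation. Interferon-stimulated genes carry 2 asterisks in HFD+EV against HFD, in HFD+EV against ND+EV and in the difference of the EV effects.

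Averaged over the injections, OAS2, an interferon-induced sensor of double-stranded RNA, rose under the high fat diet by 1.94 ± 0.35 on the log2 scale (SE; limma adjusted p = 0.0461). TOMM22 (1.55), PSMD8 (1.21), COQ10A (1.13), PERP (1.12), the pyrophosphate transporter ANKH (1.07), PCP4L1 (1.03) and FAM129A (1.03) rose, and MIR885 (-0.98), DDI1 (-0.70) and CUEDC1 (-0.61) fell. Some of these averages came mainly from the vehicle hearts. PCP4L1 had 6.25 in HFD and 4.31 in ND, and 4.59 in HFD+EV and 4.47 in ND+EV. With EV, FAM129A had 6.93 in HFD+EV and 6.64 in ND+EV, and DDI1 4.21 and 4.35. OAS2 rose under both injections (7.96 against 6.13 with vehicle, 8.49 against 6.45 with EV). Interferon-stimulated genes as a list did not pass camera in HFD against ND, with medians from -0.037 to 0.14 over the settings. Their mean score was -0.13 in HFD and -0.27 in ND, against 0.54 in HFD+EV and -0.19 in ND+EV. In all 242 probe sets passed, 178 higher and 64 lower, with 5108 at an unadjusted p under 0.05. The adjusted p values that passed lay between 0.0461 and 0.0492, close to the threshold. The count was 0 with no filter, quantile normalization or cyclic loess and without both ND replicates 1 and 3. Leaving out 1 array gave 2 without HFD replicate 1, 1256 without ND replicate 2, 1399 without HFD+EV replicate 1 and 0 without any other single array. CABP2 (-0.79) and SLA-5 (-0.71) filled the lower places and did not pass. HIF1A (0.73 ± 0.18) and ANGPT2 (0.44 ± 0.13) passed adjusted over the list alone and not over all genes (adjusted p = 0.0621 and 0.0871; ANGPT2 0.29 without HFD replicate 2), and NOS3 had -0.39 ± 0.14. Camera passed 19 lists, 17 higher and 2 lower, and 0 with an estimated correlation (smallest adjusted p = 0.1001, for interferon-stimulated genes, median 0.33).

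Averaged over the diets, interferon-stimulated genes were higher with EV than with vehicle (all 19 higher, median 0.36, camera adjusted p = 5.5e-15). With an estimated correlation the adjusted p was 0.0033. That call held in 19 of 20 settings, and not without ND replicates 1 and 3 and HFD+EV replicate 1. The average difference lay mainly under the high fat diet. The mean interferon score was 0.54 in HFD+EV and -0.13 in HFD, against -0.19 in ND+EV and -0.27 in ND. Cardiac stress genes were lower (all 13, -0.31), and respiratory chain (0.27), ribosomal protein (0.19), antigen presentation (0.18), proteasome (0.18), cell cycle (0.10) and macrophage genes (8 of 12 higher, 0.12, C1QB among them) were higher, with an adjusted p of 0.766 with an estimated correlation for all 7. Without both ND replicates 1 and 3 the ribosomal protein median turned to -0.016 (camera adjusted p = 0.795), and respiratory chain (median 0.038; 0.249), proteasome (median 0.071; 0.664), antigen presentation (0.104) and macrophage genes (0.104) did not pass. Without HFD+EV replicate 1, 13 lists passed in place of 8. Without ND replicate 1 ribosomal protein (0.476), macrophage (0.206), proteasome (0.0938), cell cycle (0.0681) and antigen presentation genes (0.0538) did not pass, and without HFD replicate 1 macrophage (0.246), cell cycle (0.229) and antigen presentation genes (0.0562) did not. Cell cycle genes also failed without ND replicate 2 (0.161) or ND+EV replicate 3 (0.169), and macrophage genes without ND replicate 2 (0.0674), ND+EV replicates 2 (0.0853) or 3 (0.108) or HFD+EV replicates 2 (0.0615) or 3 (0.0849). With limma 0 probe sets passed and 1120 had an unadjusted p under 0.05. ISG12(A) (0.84), UQCR10 of complex III (1.71), LGALS9 (0.87), STC1 (0.68), MX2 (0.93), CD209 (0.76), ARRDC2 (0.59) and RNF115 (1.09) were the higher genes of the rule. YJEFN3 (-0.69), the filamin FLNC (-0.82), PCP4L1 (-0.75), XIRP2 (-1.45), TBC1D9 (-0.80), CASQ1 (-0.65), UBAP1 (-1.85) and PDIA2 (-0.61) were the lower ones, and none passed. VEGFA had -0.42 ± 0.14 (adjusted p = 0.855).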

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

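The tests of interferon-stimulated, respiratory chain, ribosomal protein and cardiac stress genes described here were chosen after the results were seen. The counts of other splits of the arrays were chosen before. In 11 gene lists the EV effect differed between the diets by a test of the difference itself: interferon-stimulated genes (median difference 0.57), immediate early genes (0.24), respiratory chain (-0.76), ribosomal proteins (-0.67), proteasome (-0.72), TCA cycle (-0.51), heat shock (-0.45), glycolysis (-0.47), collagen and matrix (-0.56), ketone and branched-chain amino acid breakdown (-0.45) and sarcomere (-0.22). Only the first held with an estimated correlation (adjusted p = 0.0101; 0.651 for the other 10). That p ranged from 0.0053 to 0.139 over the alternatives, the highest being without ND replicates 1 and 3 and HFD+EV replicate 1. In that fit the respiratory chain, ribosomal protein, proteasome, TCA cycle and heat shock lists also failed camera, and without HFD+EV replicate 3 the immediate early median turned to -0.058.

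Interferon-stimulated genes were higher in the HFD+EV arrays. No single array carried this, since the lowest HFD+EV score was 0.46 and the highest other score -0.08. A trend with signal level is argued against, as the adjusted p with an estimated correlation was 0.00047 after cyclic loess (0.00044 to 0.104 over the alternatives). For macrophages in the tissue, 9 of the 12 measured markers were used, those with a mean signal above the median of the genes tested. The list score minus their score differed by 0.58, and by as much for 2 of 165 choices of 3 arrays (highest other 0.63). The macrophage score itself differed by 0.17, and by as much for 32 of 165 choices. C1QB, the marker with the highest mean signal, had 8.33 in HFD and 8.65 in HFD+EV. The markers thus differed less than the list. The subtraction cannot exclude macrophages as a cause, since it assumes that they raise both scores alike. The list was also picked for setting these arrays apart. By array, the list score minus the macrophage score was 0.76, 0.33 and 0.17 in HFD+EV and 0.29 on ND replicate 1. It was negative on the remaining arrays, so it did not fully set the HFD+EV arrays apart. The list score alone differed as much for 1 of 165 choices, the real one (0.74, highest other 0.49). An interferon response to EV under the high fat diet remains a candidate explanation. No test here could decide it, since it was found and tested on the same data. A shared exposure or processing batch of the 3 arrays was not tested.

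Respiratory chain and ribosomal protein genes were higher in HFD than in ND, and the EV effects on them differed between the diets, by camera. With an estimated correlation neither held (adjusted p = 0.453 and 0.753 for HFD against ND, 0.651 for the difference). Without ND replicates 1 and 3 the respiratory chain median was 0.46 against 0.95 with all arrays and the list passed camera (0.00032), with 1 ND array left, which leaves open how much these arrays made of the difference. After cyclic loess it was 0.54, so a trend with signal level may account for part of it. Cyclic loess and leaving out the 2 ND arrays were not combined, so whether both together account for the whole was not tested. For ribosomal proteins the medians were 0.057 without the 2 ND arrays (camera adjusted p = 0.986) and 0.13 after cyclic loess, so that the standing of these arrays, or a trend with signal level, could account for that difference. No biological explanation was tested.

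Cardiac stress and fetal genes were lower in HFD+EV than in HFD in all 13 members by camera, and the call did not hold with an estimated correlation (adjusted p = 0.615). Without HFD replicate 2 the camera adjusted p was 0.080 and the median -0.32 against -0.66 with all arrays, so 1 array may carry much of the difference. Atrial markers, which did not pass, were also highest on that array (score 0.76, against 0.21 on HFD replicate 1). The 2 lists share NPPA and MYL4, so their scores are not independent. NPPA had a log2 signal of 9.27 on HFD replicate 2 and 7.15 on HFD replicate 1. No biological explanation was tested.

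Other splits of the same arrays showed how often chance gives counts as large. For the mean diet effect 1 of 100 splits, the real one, gave as many genes (242, highest other 60). That share is the lowest these splits can give, so chance is argued against for that count and not excluded. The count itself was 0 without any single one of ND replicates 1 and 3, the ND+EV arrays and HFD+EV replicates 2 and 3. It was also 0 with no filter, quantile normalization or cyclic loess. Every adjusted p that passed lay between 0.0461 and 0.0492. As many lists came from 10 of 100 splits (19, highest other 21), so chance was not excluded there. For the mean EV effect chance was not excluded for lists (57 of 100 splits; 8, highest other 17). With 0 genes passed by limma (1120 at an unadjusted p under 0.05) every split gives as many (100 of 100; highest other 1), so the splits say nothing about that count. For ND+EV against ND the 10 splits were too few for a share under 0.05 (lists 8, highest other 10, 5 splits as large). The same held for HFD+EV against ND+EV (lists 6, highest other 20, 7 splits). In both comparisons such a count of lists was thus common among the splits. In these comparisons limma passed 0 genes (1758 and 1522 at an unadjusted p under 0.05), so that all 10 splits give as many by construction (highest other 3 and 0).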

How the results depend on the processing

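Cyclic loess, the fits without ND arrays 1 and 3 (with and without HFD+EV array 1) and identical probe sets counted once were chosen after the data were seen. Of the named list values under an alternative, 1564 kept their direction and side of the threshold, 470 lost the call and 2 reversed. A call can be lost with an unchanged median, as with an estimated correlation (79 calls). For named genes 7783 stayed the same, 679 were weaker, 9 reversed and 281 were stronger. Of the counts and the correlation, 257 stayed within the limit, 97 moved and 3 reversed. Where leaving out an array left 1 in a group, it was assumed to vary like the other groups. The cause of the changes given here was not tested, except that some settings have fewer arrays or probe sets. A background signal per array was not available here, so the limit from signal over background was not assessed.

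Genes that passed in HFD against ND (152) numbered 0 with no filter, eBayes with trend and robust, quantile normalization, array weights, only the groups compared, cyclic loess, without both ND arrays 1 and 3 and without these and HFD+EV array 1. They numbered 938 with a replicate block and 329 with only probe sets with 1 gene symbol. Leaving out 1 array gave 0 to 1356: 1 without ND replicate 1, 1356 without ND replicate 2, 12 without ND replicate 3, 7 without HFD replicate 1, 722 without HFD+EV replicate 1, and 0 without each other array.

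For the mean diet effect (242) the count was 0 with no filter, eBayes with trend and robust, quantile normalization, cyclic loess and without both ND arrays 1 and 3. It was 463 with the stricter filter on mean signal, 581 with each array centred, 1665 with array weights, 985 with a replicate block and 423 with only probe sets with 1 gene symbol. Leaving out 1 array gave 0 to 1399: 1256 without ND replicate 2, 1399 without HFD+EV replicate 1, 2 without HFD replicate 1, and 0 without each other array. In HFD+EV against ND+EV array weights gave 10 genes, the fit without both ND arrays 2, and leaving out 1 array 0 to 2 (2 without ND replicate 1 or HFD+EV replicate 1). In ND+EV against ND the range was 0 to 2 (2 without ND replicate 2). It was 0 to 1 in HFD+EV against HFD (1 without HFD replicate 1 or HFD+EV replicate 3), the difference of the EV effects and the mean EV effect (1 without HFD replicate 1).

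The number of lists moved too. With an estimated correlation it was 0 for ND+EV against ND, HFD against ND and the mean diet effect, and 1 elsewhere. With fry it was 0 for ND+EV against ND and 1 for HFD+EV against HFD, HFD+EV against ND+EV, the difference of the EV effects and the mean EV effect. Quantile normalization gave 5 in ND+EV against ND, 6 for the difference of the EV effects, 9 in HFD against ND, 2 in HFD+EV against ND+EV and 10 for the mean diet effect. Cyclic loess gave 5 in HFD+EV against HFD, 7 for the difference, 6 in HFD against ND, 2 in HFD+EV against ND+EV and 10 for the mean diet effect. With the stricter filter it was 12 in HFD against ND, 2 in HFD+EV against ND+EV and 12 for the mean diet effect. In HFD+EV against ND+EV no filter gave 14 and array weights 17. Without both ND arrays it was 4 in ND+EV against ND, 7 for the difference and 13 in HFD against ND, and without these and HFD+EV array 1 it was 5, 4 and 13, and 19 in HFD+EV against ND+EV.

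Leaving out 1 array gave 3 to 10 lists in ND+EV against ND (3 without ND replicate 1, 5 without ND+EV replicate 2), 7 to 14 in HFD+EV against HFD (14 without HFD+EV replicate 2) and 7 to 14 for the difference (7 without HFD+EV replicate 1). It gave 11 to 22 in HFD against ND (11 without ND replicate 1, 13 without HFD replicate 1) and 3 to 18 in HFD+EV against ND+EV (3 without ND replicate 3 or HFD+EV replicate 3, 12 without ND+EV replicate 2, 18 without HFD+EV replicate 1). The mean diet effect had 14 to 21 and the mean EV effect 6 to 13 (13 without HFD+EV replicate 1).

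The correlation of the EV effects (-0.16) was -0.0038 without both ND arrays and 0.020 without these and HFD+EV array 1; leaving out 1 array gave -0.24 to 0.015, with 0.015 without ND replicate 1 and 0.0082 without HFD+EV replicate 1. Values that reversed under cyclic loess were the sarcomere median in HFD against ND (-0.14) and in the difference of the EV effects (0.19), MYH7 (-0.10) and RPS3 (-0.0096) in HFD against ND, and GAPDH in the difference (0.044). THBS1 in HFD+EV against HFD ranged from -0.56 to 0.11 when 1 array was left out, with 0.11 without HFD+EV replicate 1, also when ND arrays 1 and 3 were left out with it, where HIF1A in the difference was 0.083. FGF2 ranged from -0.20 (without HFD replicate 1) to 0.69 in HFD+EV against HFD and from -0.018 (without HFD replicate 1) to 0.43 in the mean EV effect, where ANGPT2 ranged from -0.27 to 0.022 (without HFD replicate 2).

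Replicate numbers were checked for pairing. Residuals of arrays with the same number correlated at -0.10 to 0.33 over 15 pairs (median 0.078), 5 pairs were over 0.1, and 7 of 11 arrays correlated best with one of their own number. No chance value was computed for these counts, so the check does not exclude a processing batch tied to the number. The numbers were not taken as pairs in the main fit, and with a replicate block more genes passed in HFD against ND.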
